A study of Mus musculus with 4 samples.

How the data were processed

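Stromal vascular cells of subcutaneous fat of female mice were profiled as single cells with droplet-based 3' RNA sequencing (10x Genomics), in 4 groups: Cth+/+ and Cth-/- mice, each on a control or a cystine-free diet for 4 days. The protocol names the diet cystine free and the sample labels cysteine free; the name in the protocol was used. Per the labels, lymph nodes were removed and depots were pooled before digestion; the labels do not give the number of animals. Each group had 1 library. The deposited values are raw UMI counts per gene and barcode, which the authors made with Cell Ranger (version 3.0.0 per the file headers) on mm10, with cells already called. They were used without any change of unit.

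The libraries held 7175 (Cth+/+ control), 7312 (Cth+/+ cystine-free), 6353 (Cth-/- control) and 4394 (Cth-/- cystine-free) barcodes and 24395501, 30944977, 26278510 and 15948807 UMIs. A barcode was kept with at least 300 detected genes, 500 UMIs and at most 10% of UMIs from mitochondrial genes; 574, 458, 415 and 203 barcodes were over the mitochondrial limit and 197, 525, 144 and 90 under the gene minimum. Doublets were removed per library with Scrublet in scanpy 1.11.5 at an expected rate of 0.8% per 1000 barcodes (135, 110, 134 and 56 barcodes). This left 6290, 6273, 5678 and 4074 cells with medians of 2717, 3750, 3532 and 2670.5 UMIs.

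All kept cells were clustered together without batch integration: counts scaled to 10000 per cell, log1p, 2000 highly variable genes chosen per library and combined, 30 principal components, 15 neighbours and Leiden resolution 0.8 (leidenalg 0.10.2, igraph 0.11.9). Clusters were named from marker lists fixed before the data were examined, and clusters 7, 24 and 30 stayed unnamed. Clusters were then merged into classes after the data were seen: endothelial-like (vascular and lymphatic), phagocyte-like (macrophages, monocytes and dendritic cells) and lymphocyte-like (T cells, NK cells and innate lymphoid cells). Progenitor-like cells were also clustered alone with the same settings, and a subset was to be compared only if fewer than 3 of its 10 defining genes differed at least 1.5-fold between the Cth-/- libraries in the other subsets, a limit set after the data were seen.

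UMIs were summed per library and class and divided by the class total (CPM, UMIs per 1000000 UMIs). Ratios are log2 of CPM with a pseudocount of 1 CPM; their intervals come from the counts without the pseudocount, so at low counts a ratio can lie near or beyond the edge of its interval. Intervals are exact Poisson intervals for counts, Clopper-Pearson intervals for shares, and for differences of shares the widths of these combined in quadrature; all are 95% and cover counting error only. No test between groups was run, because cells of 1 library are not replicates of a group. A count of 0 was compared with a floor of 3 UMIs.

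The rule for named genes was fixed before the data were examined. It takes the 12 highest and 12 lowest log2 ratios of the diet in Cth-/- progenitor-like cells, 8 and 8 for the other comparisons in that class, and 5 and 5 for the diet in Cth-/- in each other class with at least 100 cells in both libraries. Genes needed at least 50 CPM and 30 UMIs in the higher library and a ratio of at least 2-fold. Against free RNA, they needed at least 1 part in 5 of the highest CPM of any named class with at least 100 cells there. The mural, Schwann, erythrocyte and adipocyte-like classes and the unnamed clusters did not enter this limit, so it does not guard against their free RNA. Mitochondrial, ribosomal, haemoglobin and immunoglobulin genes, Xist and unnamed gene models were left out of the rule. Not every gene the rule takes is printed. Members of the gene lists, cell type markers, Cth and Ucp1 could also be named; the adipocyte-like barcodes were defined after the data were seen.

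The 29 gene lists were fixed before the data were examined. A member counted as measured with at least 10 CPM in either library, members at least 1.5-fold apart were counted as a size and not as a test, and a list's median was placed among 10000 random lists of the same size matched on expression, as a description of these libraries. Counting intervals of list medians come from 500 Poisson draws. Bmp3b had no match in the annotation, Aldoa was left out because 2 gene IDs share its symbol, and Ccl21a and Atp5o have duplicate symbols. Free RNA was followed through Dcn and Col3a1 in lymphocyte-like cells and 9 adipocyte markers in all classes.

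The steps from counts to ratios were tested on simulated data. Poisson counts were drawn from the progenitor-like profile of the Cth-/- control library, at the UMI totals of both Cth-/- libraries. Of the genes, 2514 were assessed and 200 were changed by 1.5-fold to 8-fold. The draws hold counting error only, so they check the calculation and not free RNA, clustering or differences between libraries. Over all genes the median error was 0.0418 on the log2 scale and 95.0% of the intervals held the true ratio (92.0% for the 8-fold genes). A list shifted to a true median of -1.05 was found at -1.04, and 3 of 28 lists without a shift lay outside the range of 95% of random lists, with medians of at most 0.166 in size, so a percentile by itself does not single out a list. In progenitor-like cells counting gives a standard deviation of 0.069 on the log2 scale for genes over 50 CPM in the Cth-/- libraries.

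Before the data were examined, 22 alternatives were fixed: for shares, other filters, resolutions, numbers of components, doublets kept, centring per library, thinning and response genes left out; for expression, TMM factors (edgeR 4.0.16), size factors (DESeq2 1.42.0), totals without mitochondrial and ribosomal genes, other pseudocounts and minima, means over cells, doublets kept, a mitochondrial limit of 20%, values within clusters, whole-library sums and free RNA subtracted. The other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3. B cell, Schwann, mural, erythrocyte and adipocyte-like clusters were too small in some libraries for expression to be compared. Unnamed cluster 7, with 745 cells, had 4 mural markers such as Rgs5 and Notch3 in its top 10 genes and was not counted as mural. Cluster 18, which makes up the mural class with 198 cells, also had 4, so the small size of that class depends on the naming. Unnamed cluster 30, with 43 cells, had 6 B cell markers in its top 10 genes and was not counted as B cells.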

Results

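Cells of the subcutaneous fat of female mice were compared between mice with Cth (Cth+/+) and without it (Cth-/-), after 4 days on a control diet or on a diet without cystine. Cth encodes cystathionine gamma-lyase, the enzyme that releases cysteine at the end of transsulfuration, so the design asks what the stromal vascular cells express when dietary cystine, this enzyme, or both are missing. Cth gave 8 UMIs in 6290 cells of the Cth+/+ control library (0.355 CPM, UMIs per 1000000 UMIs, 95% counting interval 0.153 to 0.699) and 9 UMIs in 6273 cells of the Cth+/+ cystine-free library (0.314 CPM, 0.144 to 0.597). It gave 0 UMIs in both Cth-/- libraries (5678 and 4074 cells), where 8.11 and 4.60 UMIs would stand at the Cth+/+ rate, and the upper limits were 0.151 and 0.266 CPM. Each group had 1 library and no replicates, so no difference was tested; every interval below is a 95% interval of counting error only, and a difference between libraries cannot be assigned to the diet or the genotype alone.

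Progenitor-like cells, the fibroblast-like stem and progenitor cells of fat, made up 54.5% (53.2 to 55.8) of kept cells in the Cth-/- control library and 37.5% (36.0 to 39.0) in the Cth-/- cystine-free library, a difference of -17.0 percentage points (-19.0 to -15.04). Endothelial-like cells, which line blood and lymph vessels, were 8.44% and 23.4% of the same libraries (a difference of 14.96 points, 13.5 to 16.5). Lymphocyte-like cells (T cells, NK cells and innate lymphoid cells) were 4.00% and 7.34%, and phagocyte-like cells (macrophages, monocytes and dendritic cells) were 24.5% and 21.7%. In Cth+/+ the control and cystine-free libraries held 44.8% and 46.3% progenitor-like, 17.2% and 14.7% endothelial-like, 17.6% and 19.6% phagocyte-like and 5.76% and 4.70% lymphocyte-like cells. Epithelial-like cells were 4.72% and 4.02% in Cth+/+ and 4.19% and 3.63% in Cth-/-. The Cth+/+ endothelial difference of -2.47 points was -0.11 points when cells needed 500 genes and 1000 UMIs, and -0.33 when cells were thinned to 1000 UMIs. These are shares of cells recovered from digested tissue, in classes merged from clusters after the data were seen, and 4.85%, 5.05%, 2.31% and 3.22% of the cells (Cth+/+ control, Cth+/+ cystine-free, Cth-/- control, Cth-/- cystine-free) lay in unnamed clusters.

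**Figure D1:**
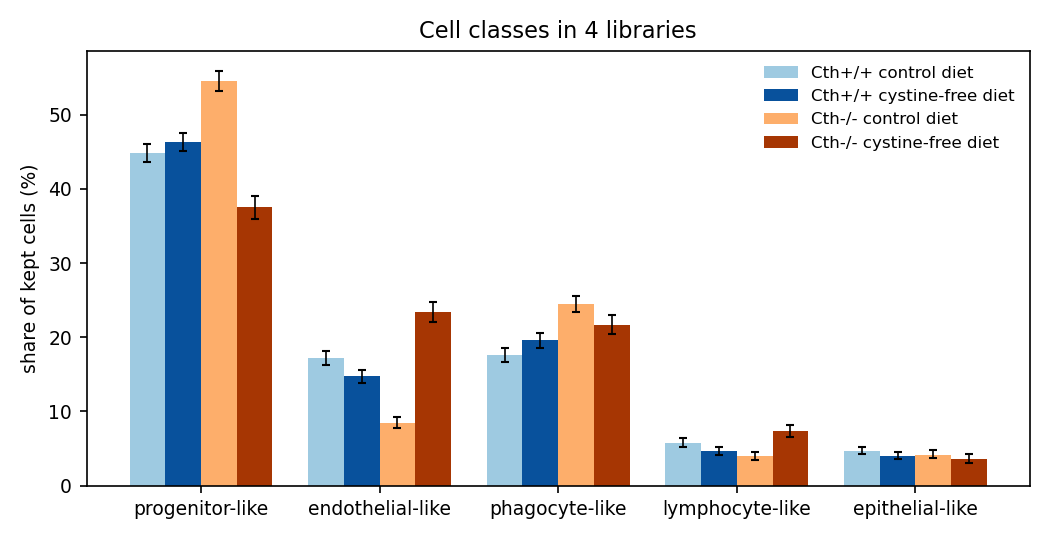
Share of kept cells (%) in 5 cell classes, 1 bar per library, with 95% Clopper-Pearson intervals (counting error only). Progenitor-like cells were 54.5% of the Cth-/- control library and 37.5% of the Cth-/- cystine-free library, and endothelial-like cells were 8.44% and 23.4%.

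The progenitor-like class was filled by different clusters in the Cth-/- libraries. On the control diet clusters 0, 3 and 4 held 36.0%, 23.2% and 21.9% of it, and on the cystine-free diet clusters 4, 5 and 0 held 41.1%, 25.5% and 19.3%. These clusters were not named as kinds of progenitor, because genes that marked some of them, such as Igfbp3 for cluster 5 and Crabp1 for cluster 0, themselves differed between these libraries over the whole class (log2 ratios 3.25 and -3.42). Progenitor-like cells clustered alone gave 17 subsets, and in 2 of them fewer than 3 of 10 defining genes also differed between the Cth-/- libraries in the other subsets, so shares of subsets were not compared. Of the 1527 progenitor-like cells of the Cth-/- cystine-free library, 577 and 280 lay in 2 subsets that held at most 7 cells of any other library.

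In progenitor-like cells of Cth-/- mice, genes of the extracellular matrix were lower on the cystine-free diet. Col3a1, the chain of fibrillar collagen III, stood at 1080.4 CPM against 9052 on the control diet (log2 ratio -3.07, -3.11 to -3.03). Postn, a matricellular protein of remodelling tissue, stood at 489 against 4486 CPM (-3.20), Col15a1 and Col18a1, collagens of basement membranes, at 58.2 against 534 (-3.18) and 44.6 against 310.1 (-2.77). Of 31 measured genes of the extracellular matrix list, 19 were at least 1.5-fold lower and 3 at least 1.5-fold higher, among them Lox, the enzyme that crosslinks collagen, at 223 against 115 CPM. Col1a1 was 693 against 3809 and Lum 593 against 2333, while Dcn, a small proteoglycan, was 10837 against 9046. The list median was -1.33, below all 10000 random lists matched on size and expression, which describes these libraries and is not a test. Within 5 progenitor clusters with at least 50 cells of both libraries the medians lay between -1.67 and -0.83, and within 4 such subsets of progenitor-like cells clustered alone between -1.33 and -0.58. The same genes reach other classes as free RNA: Col3a1 in lymphocyte-like cells was 456 CPM in the Cth-/- control library and 40.4 in the Cth-/- cystine-free library, 5.04% and 3.74% of the progenitor level.

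**Figure D2:**
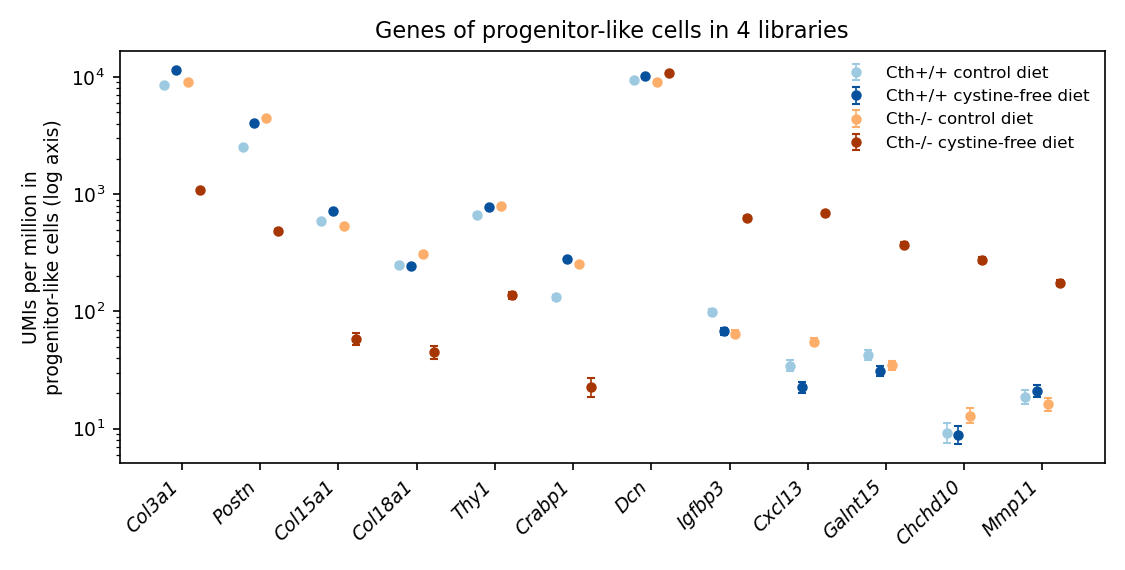
CPM (log axis) of 12 genes in progenitor-like cells, 1 point per library, with 95% Poisson intervals (counting error only). Col3a1 stood at 1080.4 in the Cth-/- cystine-free library and between 8559 and 11550 in the other libraries.

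Other genes lower in these cells on the cystine-free diet included Tagln, an actin-binding protein of contractile cells (log2 ratio -4.25, 1.95 against 54.9 CPM), Lrrc15, a membrane protein of matrix-making fibroblasts (-4.04), and Nxn, a thioredoxin-like oxidoreductase (-3.64). Crabp1, which binds retinoic acid (-3.42), Frem1, a basement membrane protein (-3.23), Angpt2, a regulator of vessels (-3.02), Itga2b, an integrin chain (-3.02), and Thy1, the surface glycoprotein CD90 (-2.52), were lower as well. Higher were Chchd10, a protein of the mitochondrial intermembrane space (log2 ratio 4.31, 4.19 to 4.63; 275 against 12.9 CPM), and Cxcl13, a chemokine that attracts B cells (3.61; 687 against 55.2). Mrgprg, a G protein-coupled receptor (3.52), Galnt15, an O-glycosylation enzyme (3.39), Mmp11, a matrix metalloproteinase (3.36), and Igfbp3, which binds insulin-like growth factors (3.25; 625 against 64.7 CPM), followed. Gstt2, a glutathione transferase (2.69), Nox4, an NADPH oxidase that makes hydrogen peroxide (2.21), Fam124a (1.87), Aox3, an aldehyde oxidase (1.74), Gpnmb, a glycoprotein of lysosome-rich cells (1.73), and Edn1, the precursor of endothelin (1.72), completed the 12 highest. Over 2132 genes with at least 50 CPM in all 4 libraries, the log2 ratios of the diet had a standard deviation of 0.50 in Cth-/- and 0.20 in Cth+/+, where counting alone gives 0.07 and 0.05.

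In Cth-/- progenitor-like cells the lists of stress and nutrient responses had different medians for the diet, and that of Atf4 targets lay inside the range of random lists. Genes of the glucocorticoid response list were higher (median log2 ratio 0.60; 9 of 16 at least 1.5-fold higher, 2 lower): Zbtb16, a transcription factor induced by the hormone, was 31.4 against 7.51 CPM, Tsc22d3 73.8 against 31.03 and Fkbp5 23.8 against 10.9, while Cdkn1c, a cell cycle inhibitor, was 123 against 535. Among Atf4 targets, the genes switched on when amino acids run short, 5 of 29 were at least 1.5-fold higher and 1 lower, and the median was 0.18 (95% of random lists: -0.19 to 0.20). Trib3, a feedback inhibitor of that response, was 20.6 against 2.37 CPM, Atf3 1210.1 against 667 and Asns, asparagine synthetase, 14.4 against 8.04, while Ddit3 was 85.5 against 98.3. The Nrf2 target median was 0.29 (4 of 17 higher, 0 lower), with Gclc, which makes the glutathione precursor, at 65.6 against 38.7. Genes of cholesterol synthesis were lower (median -0.60; 7 of 12 at least 1.5-fold lower), with Idi1, an isoprenoid isomerase, at 7.98 against 19.4 and Hmgcs1, which makes the precursor of mevalonate, at 31.7 against 55.9; within clusters the median was -0.10, with cluster medians from -0.40 to 0.22. Interferon response genes were lower (median -0.52; 9 of 21 at least 1.5-fold lower), among them Isg15 at 81.8 against 187 and Irf7 at 24.5 against 58.03. Immediate early genes, which tissue digestion also induces, were higher (median 0.53; 9 of 20 higher, 1 lower). As whole-library sums the Atf4 target median was 0.03 in place of 0.18.

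Adipocyte genes were higher in the Cth-/- cystine-free library than in the Cth-/- control library in all 5 classes with at least 100 cells in both. In progenitor-like cells Fabp4, a fatty acid carrier, stood at 1237 against 370.1 CPM and Adipoq, the adipocyte hormone adiponectin, at 12.5 against 1.19, while the regulators Pparg and Cebpa stood at 15.97 against 12.1 and 18.7 against 16.6. The adipocyte differentiation list had a median log2 ratio of 0.37 (6 of 15 at least 1.5-fold higher, 2 lower), and the thermogenic list 0.36 over 5 measured genes, inside the range of random lists. Fabp4 stood at like levels in phagocyte-like cells (1275 against 303 CPM) and lymphocyte-like cells (990.4 against 635), and within the progenitor-like cells of the Cth-/- cystine-free library at 3215 CPM in the 280 cells of subset 10, which Fabp4 and Cd36 define, and 870.2 in the others. The 9 adipocyte markers, without Fabp4, also reached classes that should lack them, as free RNA does: 339.8 CPM in progenitor-like, 514 in phagocyte-like, 420.4 in lymphocyte-like and 199 in epithelial-like cells, against 42.6, 71.6, 84.2 and 46.3 in the Cth-/- control library. Endothelial-like cells had 2429 against 1231 CPM. With the filters on mitochondrial RNA ignored, 61 barcodes of the Cth-/- cystine-free library (1.39%, 1.06 to 1.78) and 3 of the Cth-/- control library (0.0472%, 0.00974 to 0.138) had at least 5 of 9 adipocyte markers and 5 Adipoq UMIs, a rule set after the data were seen, and the Cth+/+ libraries had 0. The adipocyte-like cluster of kept cells, with medians of 582 to 760.5 UMIs per cell, went another way: it held 8, 17, 26 and 16 cells (0.127%, 0.271%, 0.458% and 0.393%; Cth+/+ control, Cth+/+ cystine-free, Cth-/- control, Cth-/- cystine-free). The 61 barcodes had a median of 25443 UMIs and 18.8% mitochondrial UMIs, and 53 of them lay over the 10% limit. Ucp1, which uncouples respiration to make heat in brown and beige fat, gave 855 UMIs over all barcodes of the Cth-/- cystine-free library and 1, 1 and 8 in the other libraries (Cth+/+ control, Cth+/+ cystine-free, Cth-/- control). Of these 855, 802 lay in the 61 barcodes, and 2 barcodes held 666.

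**Figure D3:**
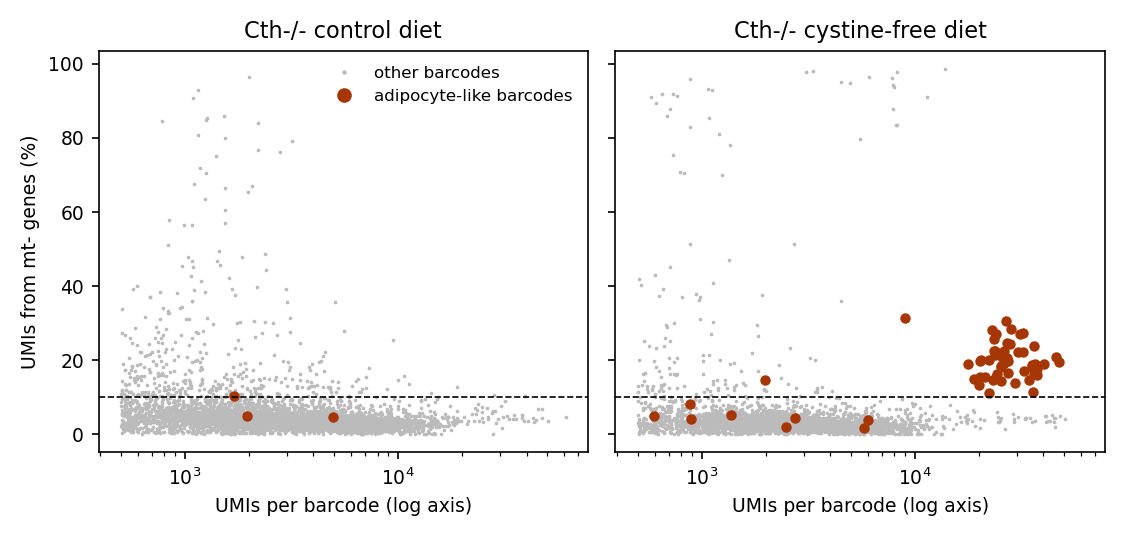
Mitochondrial share of UMIs (%) against UMIs (log axis) of every barcode of the Cth-/- libraries, with adipocyte-like barcodes as large points and the 10% limit as a dashed line. The Cth-/- control library had 3 adipocyte-like barcodes and the Cth-/- cystine-free library 61, of which 53 lay above the line.

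In Cth+/+ progenitor-like cells the cystine-free diet went with lower interferon response genes: 12 of 21 were at least 1.5-fold lower and 0 higher, with a median log2 ratio of -0.62. Isg15, a ubiquitin-like antiviral protein, was 97.6 against 212 CPM (-1.11, -1.22 to -1.02), Ifit1, which binds foreign RNA, 62.1 against 126 (-1.01), and Irf7, a transcription factor of the interferon response, 39.1 against 75.6. Higher were Nrgn, a calmodulin-binding protein (2.68; 64.9 against 9.29 CPM), Mgp, an inhibitor of calcification (1.61), Igfbp2 (1.55), Mfap4, a microfibril protein (1.49), and the heat shock gene Hspa1a (1.47). Ndufa4l2, a mitochondrial protein induced by low oxygen (1.31), and Olfml3 (1.28) were higher too. Ndufa4l2 was also among the top 10 genes of the mural cluster 18 and of unnamed cluster 7. Free RNA of these cells may enter its value, which was not tested. Extracellular matrix genes had a median of 0.25, with 5 of 31 at least 1.5-fold higher and 0 lower, and Col1a1 was 4865 against 3409 CPM. Glucocorticoid response genes had a median of 0.27, cholesterol synthesis genes 0.12 and Atf4 targets 0.04, the last being -0.02 as whole-library sums. Mitochondrial genome transcripts had a median of -0.15 and Nrf2 targets -0.06.

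On the control diet, progenitor-like cells without Cth had lower genes of cholesterol synthesis than Cth+/+ cells: 12 of 15 measured genes were at least 1.5-fold lower and 0 higher, with a median log2 ratio of -0.91. Hmgcs1 was 55.9 against 114 CPM (-1.02, -1.16 to -0.90), and Idi1 19.4 against 43.2. Within clusters the median was -0.53 (cluster medians -0.80 to -0.03), and as whole-library sums -0.48. Higher in Cth-/- were Tac1, the precursor of substance P (1.22), Mid1, a ubiquitin ligase (1.09; 70.8 against 32.8 CPM), and Ccl2, which attracts monocytes (1.03; 1358 against 663). Mid1 was also higher in endothelial-like, phagocyte-like, lymphocyte-like and epithelial-like cells of that library, and on the cystine-free diet it was 32.9 CPM in Cth-/- and 28.6 in Cth+/+ progenitor-like cells (log2 ratio 0.20; 0.69 in epithelial-like and -0.88 in phagocyte-like cells). Cytokine and chemokine genes had a median of 0.35 (5 of 16 at least 1.5-fold higher, 1 lower) and glucocorticoid response genes 0.41, while extracellular matrix genes (0.02), interferon response genes (-0.05) and Atf4 targets (-0.05) lay inside the range of random lists. Over the 2132 genes with at least 50 CPM in all 4 libraries, the log2 ratios had a standard deviation of 0.16.

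On the cystine-free diet, progenitor-like cells without Cth had lower genes of cholesterol synthesis (14 of 16 at least 1.5-fold lower, median log2 ratio -1.49) and of the extracellular matrix (19 of 31, median -1.23) than Cth+/+ cells. Nrgn gave 0 UMIs in Cth-/- and 64.9 CPM in Cth+/+, 111-fold lower against a floor of 3 UMIs (0.584 CPM). The upper counting limit of its log2 ratio, -6.50, allows a smaller fold. Lrrc15 (-4.11), Mfap4 (-4.06), Igfbp2 (-4.03), Ndufa4l2 (-4.00), Col15a1 (-3.59), Crabp1 (-3.56) and Col3a1 (-3.42, at 1080.4 against 11550 CPM) were lower. For Ndufa4l2, free RNA of mural cells may again enter the value. Cxcl13 (4.87; 687 against 22.6), Chchd10 (4.81), Galnt15 (3.55), Igfbp3 (3.19), Mmp11 (2.99), Gstt2 (2.49), Nox4 (2.36) and Mrgprg (2.23) were higher. Of the interferon response list, 3 genes were at least 1.5-fold higher and 2 lower of 21 (median -0.07). Cytokine and chemokine genes had a median of 0.60, which was -0.03 within clusters and -0.04 without a minimum expression. The diet ratio in Cth-/- minus that in Cth+/+ was -1.58 for the extracellular matrix median and -0.72 for the cholesterol synthesis median, values without a test.

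**Figure D4:**
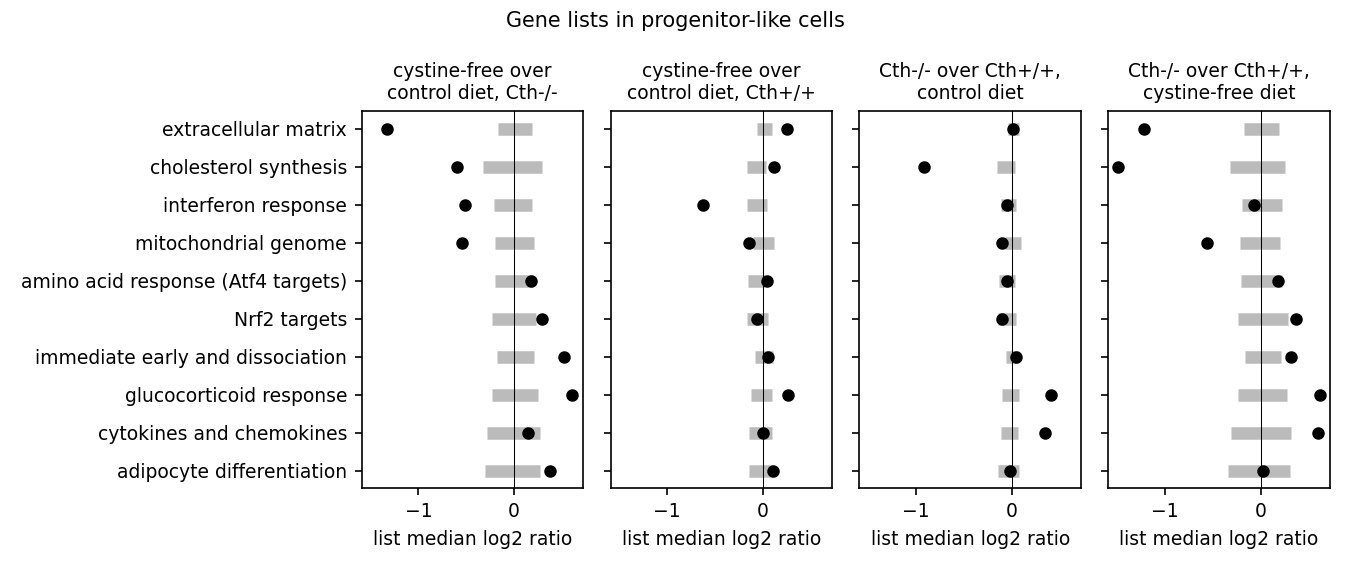
Median log2 ratio of 10 gene lists in progenitor-like cells (black points) for each diet and genotype comparison, with the range of 95% of 10000 random lists of the same size and expression (grey bars). The extracellular matrix median was -1.33 for the diet in Cth-/- and 0.25 in Cth+/+, and the interferon response medians were -0.52 and -0.62.

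In endothelial-like cells, cell cycle genes were higher on the cystine-free diet in Cth+/+ mice: 18 of 19 measured genes were at least 1.5-fold higher (median log2 ratio 1.98), with Top2a, which untangles replicated DNA, at 85.3 against 13.8 CPM and Mki67, a marker of cycling cells, at 37.6 against 5.76. Cluster 25, marked by Top2a and the tip cell gene Apln, held 73 cells of that library (7.90% of the class) and 10, 2 and 1 cells of the Cth+/+ control, Cth-/- control and Cth-/- cystine-free libraries. The median was 0.40 within clusters with at least 50 cells of both libraries, 0.30 as whole-library sums and 0.73 with a mitochondrial limit of 20%. In Cth-/-, where the median share of immediate early UMIs was 2.77% on the cystine-free and 2.51% on the control diet, the heat shock genes Hspa1a (1.90; 973 against 260 CPM), Hspa1b (1.80) and Hsph1 (2.43) and Exosc2, a part of the RNA exosome (1.94), were higher, and Mgp (-3.65), the lymphatic chemokine Ccl21a (-2.18), Mid1 (-1.95), Cytl1 (-1.86) and Col15a1 (-1.53) were lower. Cytl1 was 0.18 as whole-library sums. The histone gene Hist1h2ap was 3.02, but -0.56 as a mean over cells, -0.81 as whole-library sums and -1.65 with the limit of 20%, and the cell cycle median of 0.42 over 9 genes became -0.04, -0.74 and -2.78 under the same settings and -0.30 within clusters. Cytokine and chemokine genes had a median of -1.03 in Cth-/- and -0.18 in Cth+/+. Free RNA of another class was lower here too: the progenitor gene Dcn in endothelial-like cells was 200 against 417 CPM in Cth-/-. Dcn was also lower in phagocyte-like (284 against 533) and epithelial-like cells (192 against 389). In lymphocyte-like cells it was higher (509 against 396), so free progenitor RNA was not lower in every class. How much of the cytokine median comes from other cells is not settled. Extracellular matrix genes had a median of -1.38 in Cth-/-, which was 0.89 with free RNA subtracted, and Col3a1 was 23.5 against 450.4 CPM, beside 1080.4 against 9052 in progenitor-like cells.

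In phagocyte-like cells, interferon response genes were lower on the cystine-free diet in both genotypes: 15 of 22 were at least 1.5-fold lower in Cth-/- (median log2 ratio -1.04) and 18 of 22 in Cth+/+ (-0.77), with 0 higher in either. Rsad2, an antiviral enzyme, was 50.6 against 142 CPM in Cth-/- and 34.9 against 110.3 in Cth+/+, and Ifit1 was -2.09 in Cth-/-. As whole-library sums the medians were -0.41 and -0.45. Immediate early UMIs had a median share of 3.42% on the cystine-free and 2.41% on the control diet in Cth-/-, and of 1.84% and 1.87% in Cth+/+. Cell cycle genes were lower in Cth-/- (16 of 18, median -1.46; Top2a 18.8 against 58.5 CPM) and 0.19 in Cth+/+; within clusters the Cth-/- median was -0.35, and cycling cluster 21 held 54 cells (3.88% of the class) of the Cth-/- control and 6 (0.680%) of the Cth-/- cystine-free library. Ccl12, a chemokine for monocytes (-2.72; 25.1 against 171 CPM), Pclaf, a replication factor (-2.27), Mid1 (-2.14) and Hist1h2ap (-2.05) were lower, and Cxcl13 (5.02; 209 against 5.47), Hspa1b (2.19) and Fscn1, a gene of mature dendritic cells (2.59, but -0.48 within clusters and -0.02 as whole-library sums), were higher. Scd1 (3.39), a fatty acid desaturase, and the adipocyte gene Cfd (3.36) were higher too, and Cfd stood at like levels in lymphocyte-like cells of that library (300.5 CPM against 371), as free RNA gives. Resident macrophage genes such as Cd163, a haemoglobin scavenger (407 against 225 CPM), had a median of 0.18 in Cth-/-, but -0.35 within clusters and -0.11 with free RNA subtracted, and -0.61 in Cth+/+. The lipid-associated macrophage list had a median of 0.31 in Cth-/- (5 of 15 at least 1.5-fold higher, with Plin2, which coats lipid droplets, at 591 against 292) and -0.38 in Cth+/+. It shares Fabp4, Lpl, Cd36 and Plin2 with fat cells, and the adipocyte markers of these phagocyte-like cells were 514 against 71.6 CPM in Cth-/-. Free adipocyte RNA may therefore enter its Cth-/- value. Cholesterol synthesis genes had medians of -0.46 in Cth-/- and 0.05 in Cth+/+.

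The lymphocyte-like class of Cth-/- mice differed in make-up: T cell cluster 6 was 55.5% of it on the control diet and 77.3% on the cystine-free diet, and cluster 15, with NK cell genes such as Gzma, 44.5% and 22.7%. Over the whole class Ccr7 (log2 ratio 2.02), a homing receptor of naive T cells, and Lef1 (1.94), a transcription factor of the same cells, were higher on the cystine-free diet, and Gzmc, a granzyme of cytotoxic cells, was lower (-2.68; 72.8 against 470.3 CPM). Dapl1 was 2.58, but -0.42 within clusters and -0.33 as whole-library sums, and Ifngr2, a receptor chain for interferon gamma, was 2.00, but -0.75 as whole-library sums. Mid1 (-3.24), Samd9l (-2.37), the T cell receptor segment Tcrg-C2 (-2.10) and Fkbp2 (-2.03) were lower. Scd1 was 4.04 higher, at 218 CPM beside 231 in phagocyte-like cells. In epithelial-like cells Krtdap, Krt77, Calm4, Mt4 and Stfa3, genes of skin keratinocytes, gave 0 UMIs on the cystine-free diet. Against a floor of 3 UMIs (1.62 CPM) they were 315-fold, 266-fold, 111-fold, 69.5-fold and 64.2-fold lower. The upper counting limits of their log2 ratios, -8.00, -7.76, -6.49, -5.81 and -5.70, allow smaller folds. Krtdap was 5.82 and 0.46 CPM in the Cth+/+ libraries and 511 in the Cth-/- control library. Ctsj (5.83, from 5 UMIs in the control library), Chil1 (2.87), Ctgf (2.55), Cxcl17 (2.34) and the mucin gene Muc16 (2.29) were higher.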

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

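All tests in this part were chosen after the results were seen, except the one on dissociation stress. The patterns weighed are the lower matrix genes, the adipocyte genes and Mid1.

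Extracellular matrix genes of progenitor-like cells drew attention because the diet went with a lower list median in Cth-/- (-1.33) and a higher one in Cth+/+ (0.25), a difference of -1.58 that was not tested. A shift of cells between the 4 subsets that both Cth-/- libraries fill is argued against, since the median over these subsets was -1.10 (-1.33 to -0.58). None of them met the rule for comparing subsets, as 4 to 8 of 10 defining genes also differed elsewhere. Whether each holds the same kind of progenitor in both libraries is therefore not settled. A shift cannot be told apart from the diet for the 56.1% of cells in subsets that the Cth-/- cystine-free library fills alone. The Cth-/- control library has only 12 cells there (median -0.57 against these, -1.48 against all its progenitor-like cells). Dissociation stress that follows a cell's share of immediate early UMIs is argued against. With each library's cells split into 3 equal parts by that share, the median between the lowest parts was -1.34. These parts were not matched (median shares of 0.989% and 1.88%). The middle part of the Cth-/- control library, with a share of 2.37%, had 8643 CPM of Col3a1, against 1207 in the lowest part of the Cth-/- cystine-free library. No list median was taken between these 2 parts. A stress that acted on all cells of a library alike cannot be tested this way. Any other difference between the libraries cannot be told apart from the diet, because each group had 1 library, and the diet with loss of Cth stays open as untested.

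Adipocyte genes drew attention because data outside the kept cells held them: 53 adipocyte-like barcodes of the Cth-/- cystine-free library lay over the mitochondrial limit, and Ucp1 gave 855 UMIs over all its barcodes, against 1, 1 and 8 in the other libraries. Differentiation of progenitor-like cells as far as the 9 adipocyte markers is argued against outside subset 10. There the summed markers stood at 0.629 of their level in phagocyte-like cells. Fabp4, which is not among them, stood at 0.683, but it is in the lipid-associated macrophage list, so phagocyte-like cells are a weak baseline for it. It was 870 CPM there and 990 in lymphocyte-like cells. Earlier steps of differentiation were not tested. In the 280 cells of subset 10, which Fabp4 and Cd36 define, differentiation cannot be told apart. Fabp4 stood there at 2.52 times the phagocyte level, the summed markers at 0.835, and Lpl at 2705 against 546 CPM. Endothelial-like cells held 2429 CPM of the summed markers against 1231 in the Cth-/- control library, where the other classes held 199 to 514 against 42.6 to 84.2. An even spread of free RNA does not describe the endothelial-like level, and the source there was not tested. In the other classes free adipocyte RNA may account for the adipocyte genes, since lymphocyte-like cells held 1.24 times the progenitor level. More adipocytes in the cell suspension could be its source, as adipocyte-like barcodes were 29.4 times as frequent as in the Cth-/- control library (9.60 to 146, from 3 barcodes there), but this holds under a barcode rule set after the data were seen, and the adipocyte-like cluster of kept cells held 16 cells against 26 (45 against 42 with the limit of 20%). Whether the diet in Cth-/- mice or the handling of this 1 suspension released them was not tested.

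Mid1 was higher in all 5 classes of the Cth-/- control library than of the Cth+/+ control library. Loss of Cth regardless of diet is argued against in 4 classes, where the highest log2 ratio between genotypes on the cystine-free diet was 0.20 (progenitor-like, -0.06 to 0.46) and phagocyte-like cells had -0.88 (-1.31 to -0.52); in epithelial-like cells it stays open, since the ratio was 0.69 (0.21 to 1.23). Free RNA from 1 of these 5 classes is argued against too, since the highest of them held 2.02 times the CPM of the lowest. A source outside them was not examined. A variant carried by the animals pooled in this library was not tested. The lowest log2 ratio of the 5 classes, 1.09, restates the pattern and would be met by any cause that acts on the whole library. Loss of Cth that acts together with the diet stays open as untested.

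Other results drew attention because the diet went with opposite directions in Cth-/- and Cth+/+; none of these differences was tested. The share of endothelial-like cells differed by 17.4 points between the diet differences of the genotypes (14.96 and -2.47). The Cth+/+ value was only -0.11 with at least 500 genes and 1000 UMIs, and -0.33 with cells thinned to 1000 UMIs. The share of phagocyte-like cells differed by -4.80 points (-2.81 and 1.99). The share of lymphocyte-like cells differed by 4.39 points (3.34 and -1.05). The cholesterol synthesis median of progenitor-like cells differed by -0.72 (-0.60 and 0.12), but the Cth-/- value was -0.10 within clusters, with cluster medians from -0.40 to 0.22. The extracellular matrix median of endothelial-like cells differed by -1.60 (-1.38 and 0.22), but the Cth-/- value was 0.89 with free RNA subtracted and the Cth+/+ value -0.07 with the mitochondrial limit of 20%. In phagocyte-like cells the lipid-associated macrophage median differed by 0.69 (0.31 and -0.38). That list shares genes with fat cells, and the adipocyte markers of these cells were 514 against 71.6 CPM for the diet in Cth-/-. The cell cycle median differed by -1.65 (-1.46 and 0.19), and the Cth-/- value was -0.35 within clusters and -0.74 as whole-library sums. The resident macrophage median differed by 0.79 (0.18 and -0.61), but its Cth-/- value was -0.35 within clusters and -0.11 with free RNA subtracted, below 0 as in Cth+/+.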

How the results depend on the processing

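All alternatives were fixed before the data were examined. Of 90 alternative values of shares, 86 stayed within the counting interval of the main value. Of 143 of the list medians that lead a comparison (picked after their values were seen), 108 did and 0 were counted as changing sign. Of 870 of the other list medians, 655 did and 13 were counted as changing sign. Of 1034 of named genes, 774 did and 9 were counted as changing sign. A list median was counted as changing sign only where its main value lay outside the range of random lists. The counts for list medians therefore need not cover every median that changed sign. Shares of progenitor subsets were not compared, since at resolutions 0.4, 0.8 and 1.2 only 3 of 13, 2 of 17 and 2 of 18 subsets had fewer than 3 defining genes that also differed between the Cth-/- libraries elsewhere. The filter of 500 genes and 1000 UMIs left out 604, 326, 430 and 346 cells, thinning 598, 312, 425 and 342 (Cth+/+ control, Cth+/+ cystine-free, Cth-/- control, Cth-/- cystine-free), and the mitochondrial limit of 20% gave 6720, 6562, 5958 and 4179 cells. With 1 library per group, no alternative measures the spread between animals. The values below are the shares and leading list medians that left the counting interval, and every value counted as changing sign. Another 202 values of other list medians and 251 of named genes left the interval without such a change and are not listed. The cause was not tested.

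Shares, in points for the diet: with 500 genes and 1000 UMIs, progenitor-like -19.1 in Cth-/- and endothelial-like -0.11 in Cth+/+; thinned to 1000 UMIs, endothelial-like -0.33 in Cth+/+; at resolution 0.4, endothelial-like 12.8 in Cth-/-.

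Medians and ratios of the diet in Cth-/- unless stated. Whole-library sums, which mix all classes: in progenitor-like cells extracellular matrix -1.74, glucocorticoid response 0.41, Atf4 targets 0.026 (Cth+/+ -0.017), Cd142 program -0.18, interferon in Cth+/+ -0.45, thermogenic in Cth+/+ -0.019, cholesterol synthesis by genotype on the control diet -0.48; in endothelial-like cells cell cycle -0.74 (Cth+/+ 0.30), Hist1h2ap -0.81, Cytl1 0.18; in phagocyte-like cells cell cycle -0.74, interferon -0.41 (Cth+/+ -0.45), Fscn1 -0.02; in lymphocyte-like cells Dapl1 -0.33, Ifngr2 -0.75. Within clusters: in progenitor-like cells extracellular matrix -1.07, cholesterol synthesis -0.10 (genotype on the control diet -0.53), glucocorticoid response 0.64, cytokines by genotype on the cystine-free diet -0.034; in endothelial-like cells cell cycle -0.30 (Cth+/+ 0.40); in phagocyte-like cells cell cycle -0.35, resident macrophage -0.35, Fscn1 -0.48; Dapl1 in lymphocyte-like cells -0.42. Pseudocount 10 CPM: cholesterol synthesis -0.38 (genotype on the control diet -0.53), interferon in Cth+/+ -0.50, endothelial cell cycle in Cth+/+ 1.12, phagocyte cell cycle -0.93, phagocyte interferon -0.79 (Cth+/+ -0.71). Members with at least 50 CPM: cholesterol synthesis -0.33, glucocorticoid response 0.46, phagocyte cell cycle -0.78. No minimum: cholesterol synthesis by genotype on the control diet -0.64, cytokines by genotype on the cystine-free diet -0.036. TMM and DESeq2 factors: interferon in Cth+/+ -0.54 and -0.54 in progenitor-like, -0.65 and -0.67 in phagocyte-like cells. Means over cells: progenitor interferon in Cth+/+ -0.45, endothelial cell cycle -0.042, Hist1h2ap -0.56. Mitochondrial limit of 20%: endothelial cell cycle -2.78 (Cth+/+ 0.73), Hist1h2ap -1.65, endothelial extracellular matrix in Cth+/+ -0.067. Free RNA subtracted: extracellular matrix -1.38 in progenitor-like and 0.89 in endothelial-like cells, phagocyte cell cycle -1.75, interferon -1.17, resident macrophage -0.11.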

Other observations

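These genes were picked from the lists and the named genes after their values were seen. The inducible heat shock gene Hspa1a was higher in the Cth-/- cystine-free than in the Cth-/- control library in all 5 classes: 257 against 84.5 CPM in progenitor-like, 973 against 260 in endothelial-like, 1197 against 317 in phagocyte-like, 123 against 34.9 in lymphocyte-like and 402 against 92.3 in epithelial-like cells. In Cth+/+ the same comparison gave 216 against 77.4, 224 against 127, 330.1 against 234, 37.3 against 71.6 and 189 against 94.1, so it was lower in lymphocyte-like cells. Immediate early genes, which tissue digestion also induces, had median shares of UMIs that differed in the same comparison of Cth-/- libraries: 3.38% against 2.37% in progenitor-like, 2.77% against 2.51% in endothelial-like, 3.42% against 2.41% in phagocyte-like, 0.664% against 0.847% in lymphocyte-like and 2.35% against 0.969% in epithelial-like cells. Gdf15, a stress-induced hormone of the growth differentiation family, stood in phagocyte-like cells at 53.9, 76.8, 69.9 and 258 CPM (Cth+/+ control, Cth+/+ cystine-free, Cth-/- control, Cth-/- cystine-free), and in progenitor-like cells at 2.16, 3.32, 4.08 and 12.7. Cdkn1a, a p53 target that stops the cell cycle, stood in progenitor-like cells at 185, 152, 179 and 496 CPM. Cycling progenitor-like cells, cluster 27, numbered 21, 9, 38 and 0 in the same order, of 2819, 2905, 3095 and 1527 cells of the class. These are 0.745%, 0.310% (0.142 to 0.587), 1.23% and 0% (upper limit 0.241%), so the intervals of the cystine-free libraries overlap.

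The remaining gene lists of Cth-/- progenitor-like cells had these median log2 ratios for the diet. The lipid-associated macrophage list, which shares Fabp4, Lpl, Cd36, Plin2 and Apoe with fat cells, was 1.06 (7 of 13 measured genes at least 1.5-fold higher, 0 lower), and the Cd142 progenitor program 0.55 (4 of 8 higher, 2 lower; -0.18 as whole-library sums). Metallothioneins and zinc carriers were 0.36, lipogenesis 0.26, cysteine and glutathione metabolism 0.19 (5 of 17 higher, 1 lower), lipolysis and fatty acid oxidation 0.12, the committed preadipocyte program 0.11 and the interstitial program 0.10. In the cysteine list Cdo1, which oxidises cysteine to the taurine precursor, was 15.6 against 4.87 CPM and Mat2a, which makes S-adenosylmethionine, 455 against 257. Cytokines and chemokines were 0.14, ferroptosis genes 0.08, ribosomal proteins 0.06, autophagy and lysosome genes 0.04 and hypoxia and glycolysis genes 0.0049. Lower than 0 were p53 targets (-0.07), MHC class II (-0.08), cell cycle (-0.11), the unfolded protein response (-0.14), resident macrophage genes (-0.15), the nuclear respiratory chain (-0.25) and the mitochondrial genome (-0.55).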
